A study of Oryctolagus cuniculus with 8 samples.

How the data were processed

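RNA levels were measured in cultured rabbit cells on 1-colour Agilent arrays, with 1 array for each of 8 samples. Per the labels, total RNA was labelled with Cy3, and the samples were embryonic stem (ES) cells, induced pluripotent stem (iPS) cells made from liver and stomach cells, and the liver and stomach cells themselves. iPS cells are body cells that have been reprogrammed to a state resembling that of ES cells, which come from the embryo. The samples were placed in 4 groups of 2 from the labels: ES, early passage iPS, late passage iPS and somatic cells. Each iPS group held 1 line of liver origin and 1 line of stomach origin, and the labels give the same line names at both passages. The labels do not say which factors were used for reprogramming, and nothing in them says that replicates came from separate cultures or animals beyond the line and tissue names. The p-values therefore measure only the spread between these samples, part of which may be technical. The somatic pair is 2 tissues, and the difference between them enters the spread that all comparisons share. Across tested probes the SD of the log2 difference was 0.758 between liver and stomach cells and 0.489 between the ES lines.

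Per the file headers, the deposited values were intensities, the brightness of each spot on a linear scale, from Agilent Feature Extraction 10.5.1.1, which subtracted the local background, removed spatial trends and marked spots with uneven pixels. No scaling between arrays had been applied to these intensities. The authors' value table of the whole series was on a log2 scale. It matched log2 intensities divided by the 75th percentile of each array and then centred per probe on the median of the 8 arrays, with a correlation of 1 on every array. The median of its values lay between -0.042 and 0.342, the highest being that of stomach cells. Scale, centring and direction of that table were settled by this match, and it served as an alternative only.

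From the deposited intensities, the log2 processed signal minus the 75th percentile of each array was computed over the probes that are not controls, and the 5 spots of each of 50 probes with several spots were averaged. Levels given below are on this scale, so that 0 is the 75th percentile of the array. Each array held 45220 spots, of which 1417 were controls, and 43603 different probes. A total of 19 probes with a spot marked as uneven or outlying on any array were left out. No spot was saturated. Probes were tested where they were well above background, by the mark in the deposited files, on both arrays of at least 1 group, which left 28848 probes, of which 22111 were well above background on all 8 arrays.

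The files pair probes with accessions, not with gene symbols. Symbols were taken from a RefSeq gene table of the rabbit assembly mOryCun1.1, used only for names, without versions on either side. Of the 43603 probes, 2089 had a RefSeq accession, 29568 an Ensembl transcript and 11946 another accession. A symbol was found for 1933 probes of 680 genes, 99 probes matched a placeholder name only, and 41571 stayed unnamed here. Of the named genes, 507 were tested. Where a gene had several probes, the probe with the highest mean level over all arrays stood for it. Of the 345 named genes called between iPS and somatic cells, 192 had other tested probes and 10 of these had a probe of opposite sign. Most genes of the arrays, among them most known markers of pluripotency, are therefore not analysed here by name.

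Differences were tested with limma 3.58.1 in R 4.3.3, by linear models and empirical Bayes moderation, two-sided, with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05 on the adjusted p. For iPS against somatic, ES against somatic and iPS against ES cells, the early and late arrays of an iPS line were averaged, because they are not independent, which left 6 units in 3 groups that shared an estimate of the spread. For late against early iPS cells and for each passage against ES cells, all 8 arrays were fitted in 4 groups. The n given with iPS values is thus the number of lines. Genes named in the text were chosen by a rule: the 10 named genes with the largest rise and the 10 with the largest fall among those past the threshold whose values did not overlap, 5 and 5 for comparisons by passage, filled up by the size of the moderated statistic and given as values only where too few passed. The rule added up to 4 measured members of each gene list and a few fixed genes. A gene not well above background on any array of a group has only a bound there. Its fold is given as "at least", from the mean of the bright group over the mean, per array of the dim group, of the higher of its own signal and the lowest signal among probes well above background.

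A total of 27 gene lists with 515 symbols were written from textbook knowledge. Only 51 of these symbols had a named probe and 16 lists had any named member. The lists for the primed state, endothelium, trophectoderm, endoderm, germ cells, DNA replication and mitosis, the interferon response, MHC, oxidative phosphorylation, DNA methylation and imprinted genes had none and gave no result. The 6 lists with at least 3 tested members were tested in 4 comparisons with limma's camera, which compares a list with the other named genes, at a preset correlation of 0.01 between genes, adjusted over the 24 tests. An estimated correlation and limma's fry were alternatives. Fry asks whether the genes of a list move, on balance, in 1 direction and does not compare them with other genes. The groups, tests, lists, naming rule and most alternatives were chosen before the data were examined. Scan day as a block, the absence of scaling, the filter on probes seen on at least 5 arrays and the omission of ES arrays from the distances were chosen after seeing the data.

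The alternatives were quantile normalization, normexp background correction with an offset of 50, no scaling, no filter on dim probes, a filter on probes well above background on all 8 arrays, a trended and robust prior, the authors' log2 table, slide and scan day as blocks, all arrays as independent samples, blocks for the cell of origin or the line, and each array left out in turn. Normexp used the median signal of a spot and of its background, since the mean signal that is customary for it was not among the columns used here. The 3 slides each held more than 1 group. Slide 1 held ES replicate 1, both liver iPS arrays and liver cells, slide 2 held ES replicate 2 and stomach cells, and slide 3 held both stomach iPS arrays. Slide 1 was scanned on 1 day and slides 2 and 3 on another.

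The cell of origin pairs early with late iPS arrays, since both come from 1 line. The deviations from the group means of same-line arrays had a correlation of 0.22 across probes, against 0.02 between early iPS and somatic arrays and 0.01 between late iPS and somatic arrays. Genes and probes are not independent replicates, so correlations across them carry no p-value. The fits were tested on simulated data with the spread of these arrays, in 10 repeats with 200 changed probes among 28848. For iPS against ES cells, 6.12% of 2-fold, 73.3% of 4-fold and 92.3% of 8-fold changes were recovered, with a mean of 7.9 false calls. With only 9 changed probes, in 60 repeats chosen after seeing the data, the shares were 0%, 6.67% and 51.1%. For late against early iPS cells, with 200 changed probes split among the folds, the shares were 17%, 77.9% and 90.0%, with 7.9 false calls. For iPS against somatic cells they were 5.07%, 73.4% and 91.4%, with 6.3 false calls, and ES cells were shifted too. The last shares do not carry over to the data, where 19223 probes were called and the threshold was thus more lenient. There 13321 of the 14044 probes at least 2-fold apart passed. Camera called a moved list in 100% of 50 repeats and an unmoved list in 1.33%, over 500 simulated genes. These genes were independent, all members of the moved list shifted alike and all other genes were unchanged. Between iPS and somatic cells 345 of the 507 named genes were called, so the shares do not carry over to comparisons with somatic cells. The number of arrays, 2 per group, limits the precision of every value below.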

Results

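Expression profiles were obtained from 8 samples of cultured Dutch rabbit cells, each on 1 array of 43603 probes. The ES group held the lines rdES4 (replicate 1) and rdES2-1 (replicate 2). The iPS groups held a liver line, taken at passages 7 and 23, and a stomach line, taken at passages 6 and 22. The somatic group held the liver cells (replicate 1) and the stomach cells (replicate 2). Per the labels, ES and iPS cells were grown in stem cell medium and the somatic cells in another medium, so medium and cell type go together in every comparison with somatic cells. The 75th percentile of the signal lay between 273.8 and 341.3 on the 6 arrays of ES and iPS cells and was 163.5 for liver cells and 154.7 for stomach cells. Between 62.38% and 64.65% of the probes were well above background on ES and iPS arrays, against 57.79% for liver cells and 58.42% for stomach cells.

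The 6 arrays of ES and iPS cells resembled each other far more than they resembled the somatic arrays. Across the 28848 tested probes, the 15 pairs of ES and iPS arrays correlated at r between 0.977 and 0.992, and the 12 pairs of an ES or iPS array with a somatic array at r between 0.798 and 0.818. Liver and stomach cells correlated at 0.974, the ES lines at 0.989, and the iPS lines at 0.988 early and 0.992 late. The first principal component held 84.8% of the variance and separated the somatic arrays from all others, and the next held 4.41%.

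**Figure D1:**
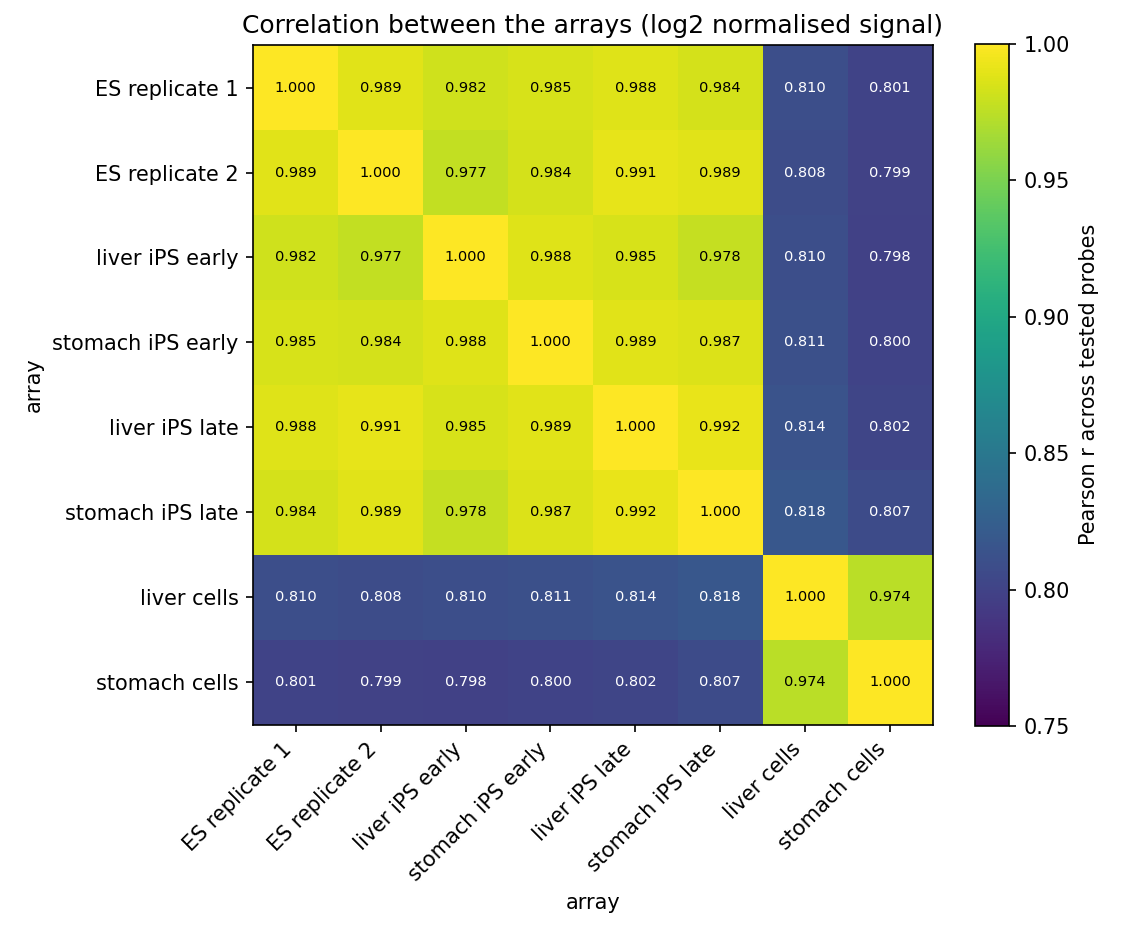
Pearson correlation of the log2 normalised signal across tested probes, with the 8 arrays on both axes and the value of r in each square. Pairs of ES and iPS arrays lie between 0.977 and 0.992, and pairs with a somatic array between 0.798 and 0.818.

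iPS cells were compared with somatic cells to see what differed after reprogramming. POU5F1, the transcription factor Oct4 that maintains pluripotency, was 1900-fold higher in iPS cells, with a level of 7.35 ± 0.0027 (SD, n = 2 lines) against -3.54 ± 0.11 (SD, n = 2) in somatic cells (log2 difference 10.89 ± 0.19 SE, adjusted p = 6.29e-05). The labels do not name the reprogramming factors, so whether its probe could also detect an introduced transcript is not known. SAA3, an acute phase protein of the serum amyloid A family, was at least 6459-fold lower in iPS cells, where it was not well above background on any array (adjusted p = 9.11e-05). Decorin (DCN), a proteoglycan of connective tissue, was at least 1269-fold lower (adjusted p = 9.46e-05), and the chemokine genes GRO-A and CCL2 were lower by 1790-fold and 675-fold. GRO-A was at least 1492-fold lower with its dim iPS arrays raised to the lowest signal well above background. In all, 19223 of 28848 probes (66.6%) passed the threshold, 9872 higher and 9351 lower in iPS cells, and 13321 of them differed at least 2-fold. Of the 507 named genes, 112 were higher and 233 lower, but without scaling between arrays 209 were higher and 129 lower, and with normexp 94 and 324.

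Both measured members of the pluripotency list rose in iPS cells, and the count adjusted over the list alone was also 2 of 2. POU5F1, the only reprogramming factor measured by name, was described above. PODXL, a sialomucin found on pluripotent cells, had a log2 difference of 8.41 ± 2.17 (SE, adjusted p = 0.0204), with levels near 7.3 on every iPS array, 2.34 in liver cells and -4.54 in stomach cells, where it was not well above background. Among other named genes with the largest rises were TNNC2, which encodes a troponin C of fast skeletal muscle (at least 189.8-fold), LIPH, a lipase (at least 66.5-fold), CKMT2, a mitochondrial creatine kinase (at least 24.6-fold), the scaffold gene PDZK1 (59.0-fold), the endothelin receptor gene EDNRB (at least 13.2-fold) and CXADR, a cell adhesion protein of epithelial junctions (39.2-fold). The prolactin receptor gene PRLR and the potassium channel gene KCNS3 rose by 5.40 ± 0.96 and 5.33 ± 1.37 (SE) on the log2 scale, each well above background on 1 of the 2 somatic arrays. PDZK1 likewise was measured on only 1 of the 2 somatic arrays. With the dim somatic array raised to the lowest signal well above background, PRLR was at 4.33 and KCNS3 at 4.27.

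All 8 measured members of the inflammation list fell in iPS cells, and the same number fell when adjusted over the list alone. The median log2 difference was -8.60, and -8.21 with the genes that have only a bound set to it. Besides SAA3 and CCL2, the list held PTGS2, the inducible cyclooxygenase (-8.51 ± 0.23 SE), VCAM1, an adhesion molecule for leukocytes (-9.72 ± 0.48), IL6 (at least 125.4-fold lower), IL1RN (-7.92 ± 0.73), IL1A (-7.61 ± 1.80, measured on 1 of 4 iPS arrays) and CXCL8 (-2.90 ± 0.76). VCAM1 was well above background on 2 of the 4 iPS arrays, both of late passage. With the dim iPS arrays raised to the lowest signal well above background, the differences were -8.58 for VCAM1 and -6.17 for IL1A, and the median with bounds stayed at -8.21. Against the other named genes, camera gave adjusted p = 0.0213 for the list, and adjusted p = 0.555 with an estimated correlation. Fry gave adjusted p = 5.65e-05. GRO-A, a chemokine gene whose symbol matched none in the lists, was measured on 2 of the 4 iPS arrays. The aspartic protease gene CTSE and the oxidase gene AOX1 were at least 108.6-fold and at least 106.7-fold lower.

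All 4 measured members of the fibroblast and mesenchyme list fell, also when adjusted over the list alone, with a median of -7.66. These were DCN, MGP, an inhibitor of calcification (-9.33 ± 0.78 SE, measured on 3 of 4 iPS arrays), CAV1, the coat protein of caveolae (-5.99 ± 0.34) and MMP2, a gelatinase (-2.18 ± 0.20). The list missed the threshold of camera (adjusted p = 0.0992, and adjusted p = 0.555 with an estimated correlation), and fry gave adjusted p = 1.6e-05. All 4 measured members of the smooth muscle list fell as well, also when adjusted over the list alone, though 3 did with quantile normalization and 2 without scaling: ACTA2, smooth muscle actin (-5.64 ± 0.75 SE), TPM2 (-4.50 ± 0.40, measured on 1 of 4 iPS arrays), TPM1 (-1.39 ± 0.33) and CALD1 (-1.24 ± 0.38). With dim iPS arrays raised in the same way, MGP was at -9.17 and TPM2 at -3.67, and the medians of the fibroblast and smooth muscle lists were -7.58 and -2.53. Camera gave adjusted p = 0.337 for that list, adjusted p = 0.884 with an estimated correlation, and fry 0.0221. CALD1 was not called with quantile normalization (-1.04, adjusted p = 0.0681), nor without ES replicate 1 (adjusted p = 0.0531), ES replicate 2 (0.0529), the late liver iPS array (0.0832), the late stomach iPS array (0.0557) or the liver cells (0.0816).

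Of 6 measured glycolysis genes, 4 fell and 2 did not pass, with the same counts adjusted over the list alone. Both with normexp and without scaling, 1 was higher and 4 were lower. GPI (-2.60 ± 0.15 SE), ALDOA (-2.19 ± 0.18), GAPDH (-1.88 ± 0.18) and LDHA (-1.68 ± 0.13) are enzymes of the pathway, and SLC2A1, a glucose transporter, was at 0.57 ± 0.29 (adjusted p = 0.137) and PFKP at -0.66 ± 0.28 (adjusted p = 0.0924). Camera gave adjusted p = 0.337 (0.748 with an estimated correlation) and fry 1.16e-04. Of 5 reference genes, HPRT1 (1.17) and PPIA (0.53) were higher and GAPDH, EEF1A1 (-0.89) and ACTB (-0.86) lower, with the same counts adjusted over the list alone. With quantile normalization ACTB (-0.04) and EEF1A1 (-0.11) did not pass, and GAPDH stayed lower. The reference list had a median of -0.86 and a mean of -0.39, while camera, which sets it against the other named genes, placed it upward (adjusted p = 0.949, and 0.952 with an estimated correlation). Fry gave 0.0149 for it.

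Markers of the tissues of origin were few. Of 5 measured hepatocyte genes, TF, the iron carrier transferrin, was higher in iPS cells (2.95 ± 0.43 SE, adjusted p = 0.00307), RBP4, the retinol carrier, was lower (-3.15 ± 0.62, adjusted p = 0.00837), and 3 did not pass: APOE (-1.15 ± 0.70), HPX (-1.04 ± 0.72) and HP (-0.54). The counts adjusted over the list alone were the same. The median was -1.04 and the mean -0.59, while camera placed the list upward (adjusted p = 0.949, 0.952 with an estimated correlation, fry 0.779). Without the liver cells, APOE (-2.21, adjusted p = 0.00402) and HPX (-2.13, adjusted p = 0.00309) passed, and HPX also did with normexp (-0.90, adjusted p = 0.00785). ALB, the gene of serum albumin, was not well above background in any group, liver cells included. Of the gastric genes, ATP4A, a subunit of the acid pump, was higher (0.73 ± 0.19, adjusted p = 0.0203, measured on 1 of 2 somatic arrays), was lower with normexp (-0.45) and did not pass without the liver cells (adjusted p = 0.067). PGC, a pepsinogen gene, did not pass (0.37 ± 0.17, adjusted p = 0.107), but did with quantile normalization (0.57, adjusted p = 0.0333) and without the early liver iPS array (0.59, adjusted p = 0.0124), and was lower with normexp (-0.52, adjusted p = 0.00425). ATP4B was not well above background in either group.

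Markers of other lineages were represented by 1 or 2 genes each. CD14, a receptor of monocytes and macrophages, was lower in iPS cells (-3.27 ± 0.42 SE, adjusted p = 0.00197), and CD3E was not well above background in iPS or somatic cells. Haemoglobin alpha (HBA) was lower (-1.03 ± 0.17), though it was not called without scaling. HBB2, measured on 1 of 2 somatic arrays, did not pass (1.12 ± 1.76, adjusted p = 0.594). It passed without the liver cells (adjusted p = 0.0071), where the remaining somatic array was not well above background. PAX6, a transcription factor of neural and eye development, was lower (-3.55 ± 0.82, adjusted p = 0.0139). KLF5, a factor of the naive state, was at -0.84 ± 0.30 (adjusted p = 0.0571) by its brightest probe. It was lower without the early liver iPS array (-1.16, adjusted p = 0.00572) and with normexp (-0.71, adjusted p = 0.000927), and 1 of its 3 other tested probes had the opposite sign. Over its list alone it was lower too, but it was the only tested member, so that its p was not adjusted there. CLDN1, a tight junction gene, did not pass (adjusted p = 0.125), was lower with normexp (adjusted p = 0.00115) and was not well above background in somatic cells. GSC, a factor of the early mesoderm, was at -0.96 ± 1.70 (adjusted p = 0.638, measured on 1 of 2 somatic and 3 of 4 iPS arrays) and passed without the liver cells (-3.63, adjusted p = 0.00176) and with normexp (-1.13, adjusted p = 0.0149), but as higher without the stomach cells (adjusted p = 0.0123), where the remaining somatic array was not well above background.

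The number of higher and lower probes depended on the scaling. Higher probes made up 51.4% of calls with scaling to the 75th percentile, 55.5% with quantile normalization, 33.2% with normexp (7541 higher, 15191 lower), 82.5% without scaling (16900 higher, 3587 lower) and 38.7% without the filter on dim probes (9532 higher, 15107 lower). The median log2 difference over all tested probes was 0.017 with scaling to the 75th percentile, 0.111 with quantile normalization, -0.402 with normexp and 1.03 without scaling. The pluripotency, fibroblast and inflammation lists kept their direction under each scaling, with 1 member of the inflammation list no longer called without scaling. With slide as a block, 9916 probes were called, 5273 higher and 4643 lower, of which 9801 were also called without the block. Slide 3 held only stomach iPS arrays, so with this block the iPS values rest on the liver line alone, with fewer degrees of freedom. The median absolute log2 difference over all tested probes was 0.97 (early) and 0.974 (late) between the liver iPS arrays and the liver cells, all on slide 1, and 1.046 (early) and 1.027 (late) between the stomach iPS arrays and the stomach cells, which were on different slides.

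**Figure D2:**
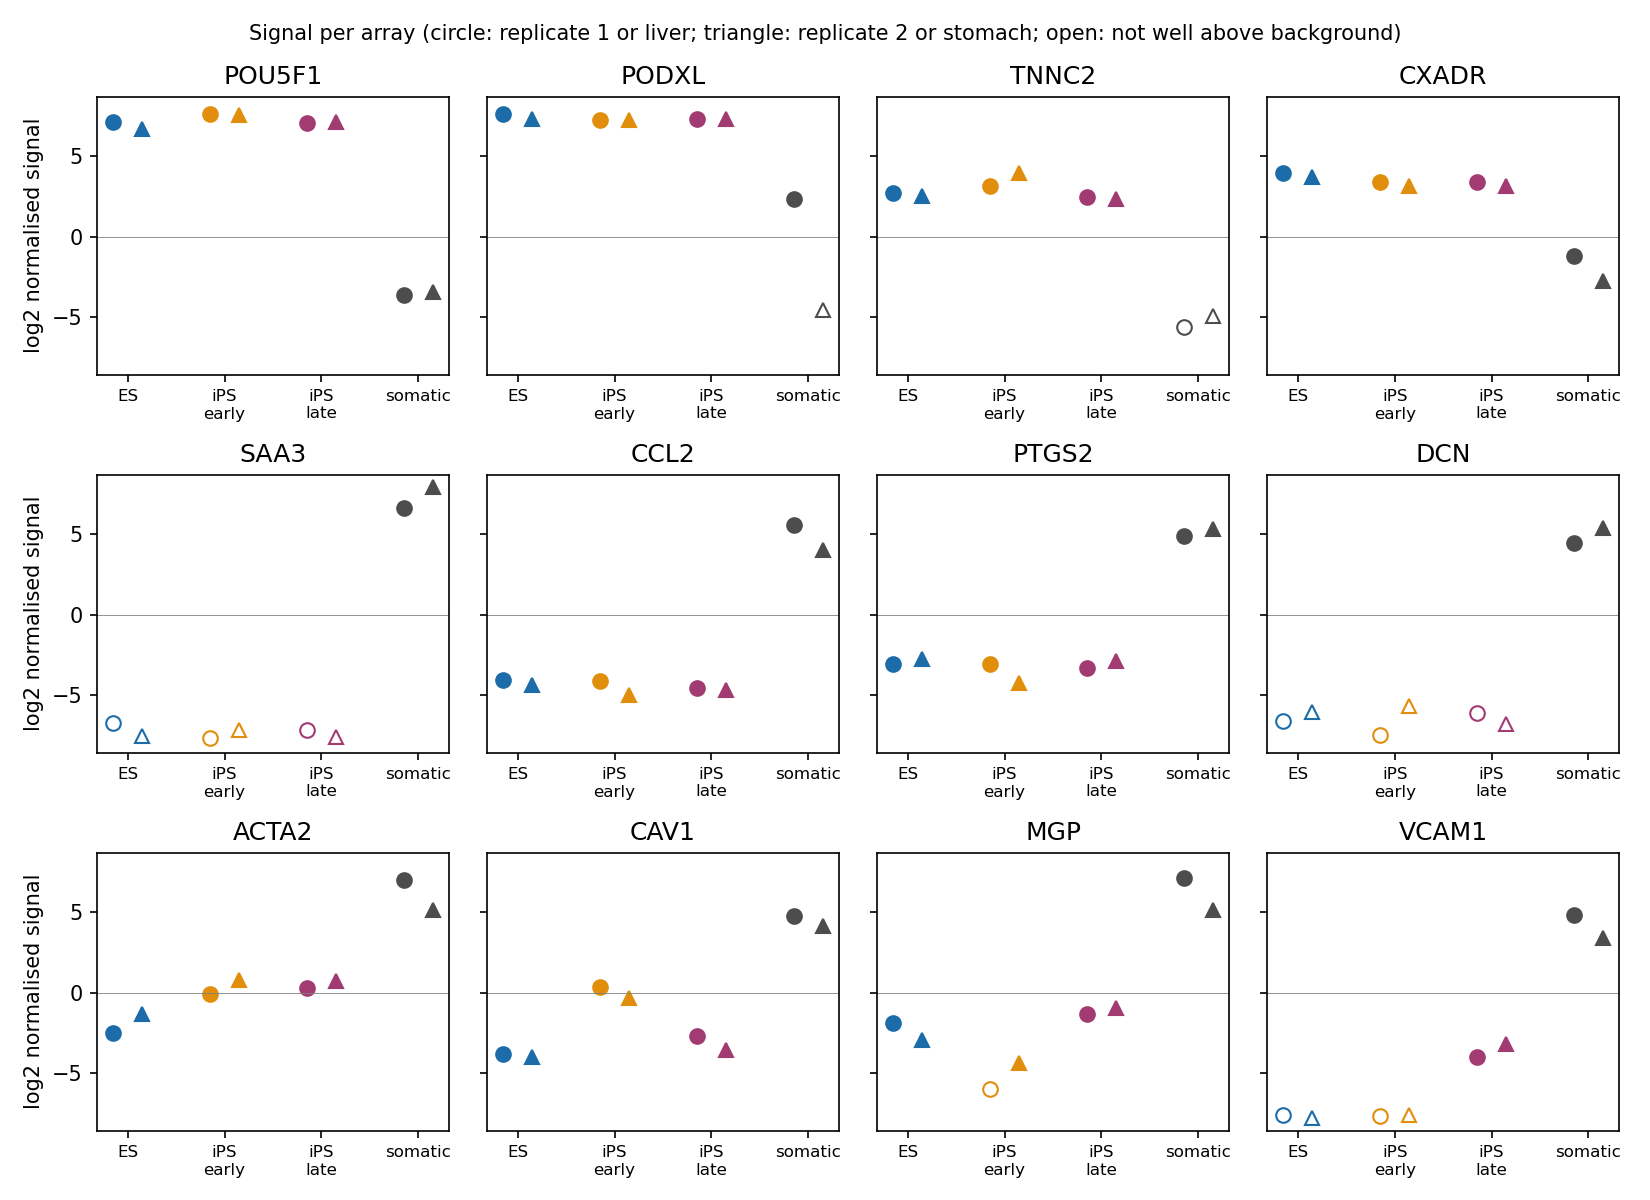
Log2 normalised signal of 12 named genes on each array, by group on the horizontal axis, with circles for replicate 1 or liver, triangles for replicate 2 or stomach, and open symbols where the probe was not well above background. POU5F1 lies near 7 on all ES and iPS arrays and at about -3.54 in somatic cells, and CAV1 differs between early and late iPS arrays by -3.03 in the liver line and -3.26 in the stomach line.

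ES cells were set against the same somatic cells to show which differences accompany the pluripotent state in cells that were not reprogrammed. POU5F1 was 1407-fold higher in ES cells (10.46 ± 0.19 SE, n = 2 lines against 2 somatic samples, adjusted p = 5.82e-05), PODXL was higher by 8.57 ± 2.17 on the log2 scale (adjusted p = 0.0199), and TNNC2, LIPH and CKMT2 were at least 146.4-fold, at least 59.4-fold and at least 22.7-fold higher. SAA3 was at least 6875-fold lower, GRO-A at least 2587-fold, DCN at least 1350-fold and VCAM1 at least 762.5-fold lower. A total of 18447 probes (63.9%) passed, 9883 higher and 8564 lower, and of the named genes 108 were higher and 217 lower, against 203 higher and 133 lower without scaling and 92 and 306 with normexp. Leaving out ES replicate 1 or replicate 2 ended the call of PODXL (adjusted p = 0.0876 and 0.0809).

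Both pluripotency genes rose, and 7 of 8 inflammation genes fell, with the same counts adjusted over the list alone. The exception was CXCL8 (-1.76 ± 0.76 SE, adjusted p = 0.0952), though all 8 fell with normexp. The median of the inflammation list was -8.50 (-7.86 with genes at their bounds), and camera gave adjusted p = 0.0213 for it, and adjusted p = 0.555 with an estimated correlation. All 4 fibroblast genes fell, among them CAV1 (-8.37 ± 0.34) and MGP (-8.59 ± 0.78), with camera adjusted p = 0.088 (0.555 with an estimated correlation). All 4 smooth muscle genes fell, though 2 did without scaling, among them ACTA2 (-7.99 ± 0.75), with camera adjusted p = 0.322 (0.884 with an estimated correlation). CALD1 (-1.68) lost its call without ES replicate 2 (adjusted p = 0.0759), and TPM1 (-1.28) without ES replicate 1 (0.0511) or replicate 2 (0.103). BDKRB1, a receptor for kinins, fell as well (-9.22), as did PTGS2 (-8.04) and CCL2 (-9.03). IL6 and CTSE were at least 133.5-fold and at least 115.6-fold lower.

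Of the glycolysis genes, SLC2A1 rose in ES cells (0.94 ± 0.29 SE, adjusted p = 0.0362), GPI, ALDOA, GAPDH and LDHA fell, and PFKP was at -0.81 ± 0.28 (adjusted p = 0.0539) but lower when adjusted over the list alone (camera adjusted p = 0.337, 0.748 with an estimated correlation). TF rose by 4.05 ± 0.43 and RBP4 fell by 3.65 on the log2 scale, and the other 3 hepatocyte genes did not pass (camera adjusted p = 0.949). Reference genes were higher for HPRT1 (1.00), lower for GAPDH, ACTB (-0.80) and EEF1A1 (-0.82) and not called for PPIA (0.36), with camera adjusted p = 0.949, and ACTB (-0.06) and EEF1A1 (-0.03) did not pass with quantile normalization. Of the 5 reference genes, 2 were higher and 1 lower both with quantile normalization and without scaling, and 2 higher and 3 lower with normexp. Both gastric genes were higher, ATP4A by 0.78 and PGC by 0.60, and both were lower with normexp, at -0.35 and -0.43. ATP4A did not pass without ES replicate 1 (adjusted p = 0.081), ES replicate 2 (0.0569) or the liver cells (0.0558), and PGC did not pass without any 1 of ES replicate 1 (0.0987), ES replicate 2 (0.0971), the early stomach iPS array (0.149), the late liver iPS array (0.131) or the stomach cells (0.0823). CD14 (-3.30) and HBA (-0.90) were lower, though HBA was not called without scaling. PAX6 (-0.87 ± 0.82), HBB2, GSC, KLF5 and CLDN1 did not pass. Without the liver cells GSC (-2.97), APOE (-2.05) and HPX (-1.79) passed, and without the stomach cells HBB2 did (-3.23). As higher, against a somatic array not well above background, GSC passed without the stomach cells (adjusted p = 0.00517) and HBB2 without the liver cells (0.0355). With normexp GSC (-0.91), HBB2 (-0.93), HPX (-0.68) and KLF5 (-0.65) passed, and so did CLDN1 as lower (adjusted p = 0.00346), and KLF5 (-0.82) also did without the early liver iPS array (adjusted p = 0.0191) or the late stomach iPS array (0.042). The largest rises also included PDZK1 (6.04), CXADR (5.84), EDNRB (at least 16.5-fold), the lens gene LIM2 (at least 9.33-fold) and the carbonic anhydrase gene CA4 (at least 9.73-fold). Higher probes were 53.6% of calls, 33.9% with normexp, 81.5% without scaling and 40.01% without the filter on dim probes.

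The same genes largely set ES and iPS cells apart from somatic cells. Of the 18447 probes called in ES against somatic cells, 17158 (93.0%) were called in the same direction in iPS against somatic cells and 9 in the opposite direction. A total of 9095 probes were higher in both, where independent lists would share 3382, and 8063 were lower in both, where 2776 would be shared. The log2 differences correlated at r = 0.98 across probes, with a covariance of 3.88. Both comparisons use the same somatic arrays: unchanged groups simulated against them, in 100 draws, gave r = 0.5, a covariance of 0.054 and 0 shared calls. With liver cells as the control of iPS cells and stomach cells as that of ES cells r was 0.916, and with the controls exchanged 0.907.

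**Figure D3:**
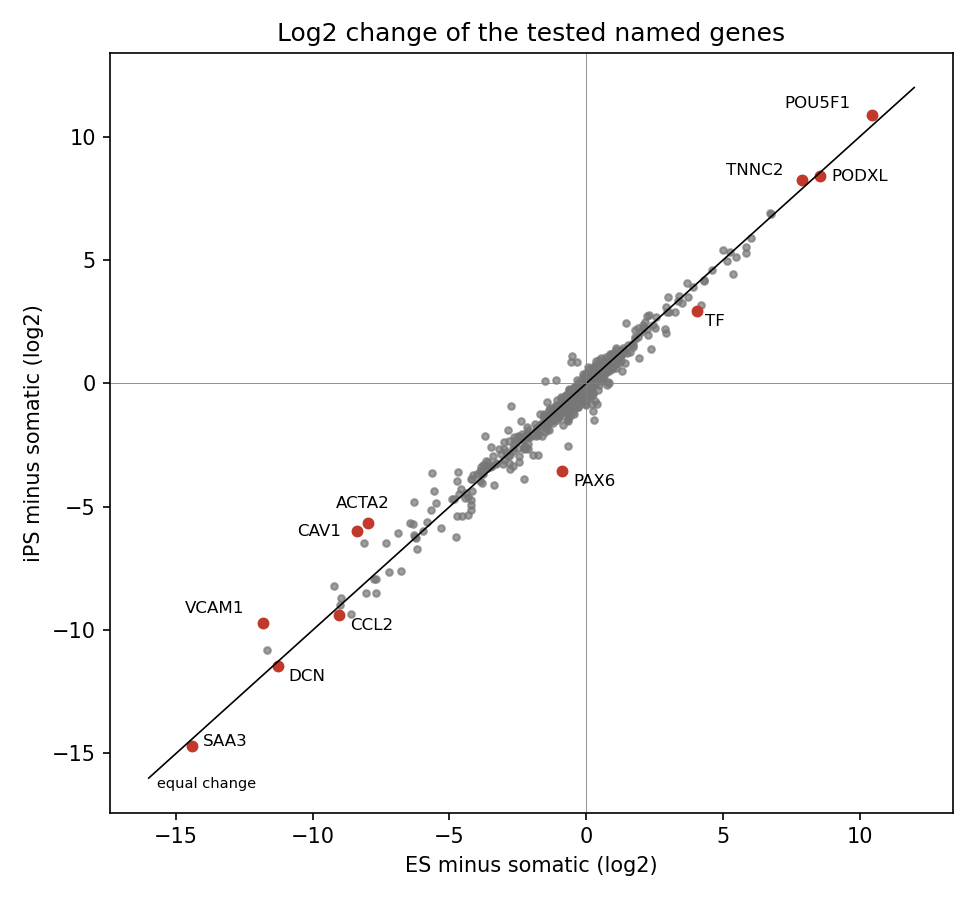
Log2 difference of each of 507 named genes between iPS and somatic cells (vertical axis) against that between ES and somatic cells (horizontal axis), 1 point per gene, with the line of equal change. Genes not well above background in a group are drawn at their measured values, POU5F1 lies at 10.46 and 10.89, CCL2 at -9.03 and -9.40, and CAV1 and ACTA2 lie above the line by 2.38 and 2.36.

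iPS cells were compared with ES cells to find genes that differ between these kinds of pluripotent cell. No named gene and none of the 28848 probes passed the threshold with limma (0 calls, smallest adjusted p = 0.0924, 2139 probes at an unadjusted p under 0.05). POU5F1 differed by 0.43 ± 0.19 (SE, n = 2 lines each, adjusted p = 0.698) and PODXL by -0.16 ± 2.17 (adjusted p = 0.994), and a difference within these errors was not detectable. The error of PODXL comes from the somatic arrays (SD 4.87), which share the estimate of the spread, while its SD was 0.0042 in iPS and 0.23 in ES cells. Among named genes measured in both groups by their brightest probe, the largest values above ES cells were those of CAV1 (2.38 ± 0.34, adjusted p = 0.402) and ACTA2 (2.36 ± 0.75, adjusted p = 0.606). The paraoxonase gene PON3, not well above background in ES cells, was at least 2.65-fold higher (adjusted p = 0.458). Values below ES cells included PAX6 (-2.68 ± 0.82, adjusted p = 0.591, measured on 3 of 4 iPS arrays), the transporter gene SLC47A2 (-1.37 ± 0.34, measured on 3 of 4 iPS arrays) and TF (-1.10 ± 0.43, adjusted p = 0.671). PAX6 was lower over its list alone, but it was the only tested member, so that its p was not adjusted there.

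Of the gene lists, camera called none between iPS and ES cells, and fry called the fibroblast list. The smooth muscle list had a median of 0.29 (0.22 with genes at their bounds, camera adjusted p = 0.322, and 0.884 with an estimated correlation). The fibroblast list had a median of -0.11 (-0.02 with genes at their bounds) and a mean of 0.36, with CAV1 higher when adjusted over the list alone (camera adjusted p = 0.565, fry 0.027). The inflammation list had a median of -0.32 (-0.30 with genes at their bounds), the hepatocyte list -0.16, the glycolysis list 0.03 and the reference list -0.04, the last with a mean of 0.03. A total of 824 probes (2.86%) differed at least 2-fold, against 14044 (48.7%) between iPS and somatic cells. With slide as a block the comparison rests on the liver iPS line alone, with fewer degrees of freedom, and the count was 0. The count of 0 was also found with quantile normalization, normexp, each filter, the trended prior, scan day as a block, and the authors' table. It was 6, all lower in iPS cells, when the 8 arrays were taken as independent or line was a random block, 12 without ES replicate 1 and 35 without ES replicate 2, where the remaining ES array was assumed to vary like the other groups.

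Late and early passages were compared within the iPS cells to follow the lines in culture. No named gene passed by its brightest probe. CAV1 had a log2 difference between late and early passage of -3.03 in the liver line and -3.26 in the stomach line (-3.14 ± 0.39 SE, n = 2, adjusted p = 0.195). Of its 6 other probes 1 was called (at least 2.21-fold lower, adjusted p = 0.0381), which was not well above background on the late arrays. All CAV1 probes were lower at late passage, by measured values from -2.86 to -3.91 in the liver line and from -2.43 to -3.26 in the stomach line. Most of them were not well above background on the late arrays. MGP differed by 4.05 ± 0.81 (adjusted p = 0.395), was measured on 1 of the 2 early arrays and was 3.39 higher in the stomach line and at least 16.6-fold higher in the liver line. VCAM1 had a difference of at least 3.42-fold (adjusted p = 0.17) and was well above background on both late arrays and neither early array. PAX6, measured on 1 of the 2 early arrays, differed by 2.99 ± 1.02 (adjusted p = 0.559), and POU5F1 was at -0.49 ± 0.18 (adjusted p = 0.563). VCAM1 was higher when adjusted over the inflammation list alone. PAX6 was higher and POU5F1 lower at an unadjusted limma p under 0.05, each as the only tested member of a list. Over the pluripotency list alone POU5F1 did not pass. The beta3 integrin gene ITGB3 was at 1.35 ± 0.28 (adjusted p = 0.403).

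Among all probes, 8 passed between late and early iPS cells, 2 higher and 6 lower (2413 at an unadjusted p under 0.05), but with normexp 6 passed, 4 higher and 2 lower, of which 1 was among the 8. The named genes among them, which were singled out after their values were seen, were the dimmer CAV1 probe and a DCN probe that was at least 3.37-fold higher at late passage (adjusted p = 0.0385) and not well above background on the early arrays. The brightest DCN probe was not well above background in any iPS group, and none of the other 5 DCN probes was called. For early iPS against ES cells 12 probes passed, 4 higher and 8 lower (3343 unadjusted), and for late iPS against ES cells 6 passed, 1 higher and 5 lower (2206 unadjusted). A pair of CAV1 probes, not well above background in ES cells, was higher in early iPS cells (at least 18.04-fold and at least 2.33-fold, each with adjusted p = 0.0208), and the brightest CAV1 probe had 3.95 ± 0.39 (adjusted p = 0.059). The DCN probe was at least 3.62-fold higher in late iPS than in ES cells (adjusted p = 0.0396), where it was not well above background. Other named values for early iPS against ES cells were -4.18 ± 1.02 for PAX6 (measured on 1 of 2 early arrays) and at least 2.85-fold for GRO-A, and for late iPS against ES cells at least 3.68-fold for VCAM1, -1.02 ± 0.17 for PLA2R1 and -0.96 ± 0.17 for KAP6.1.1, none of which passed.

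The probes called by passage were each well above background on between 2 and 6 of the 8 arrays, and their counts changed with the processing. With only probes well above background on all 8 arrays, or with slide as a block, each of the 3 counts was 0, and with the cell of origin as a block the count for late against early iPS cells was 0. The slide block leaves fewer degrees of freedom. Its counts of 0 against ES cells show little, since the stomach line had no ES array on its slide. For late against early iPS cells both lines count, since the arrays of a line shared a slide. The calls of that comparison came from a fit without such pairing, and none was made with it. Counts for late against early cells ranged from 0 without either ES array to 88 (84 lower) without the early liver iPS array and 101 (72 lower) without the early stomach iPS array, but the direction turned without the late liver array (47, of which 38 higher) and the late stomach array (47, of which 45 higher), and the count was 1 without either somatic array. Counts for early iPS against ES cells were 109 (98 lower) without ES replicate 1, 83 (78 lower) without ES replicate 2, 102 (84 higher) and 108 (62 higher) without the early liver and stomach arrays, 0 without either late array and 20 without the liver cells. Counts for late iPS against ES cells were 78 (76 lower) and 82 (77 lower) without ES replicate 1 and 2, 48 (40 higher) and 50 (47 higher) without the late liver and stomach arrays, 0 without either early array and 1 without either somatic array. In each such fit that left a group with 1 array, that array was assumed to vary like the others.

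No list was called by passage with camera or fry. The fibroblast list had a median of 0.01 (-0.07 with genes at their bounds) and a mean of 0.23 with camera placing it downward (adjusted p = 0.949), the inflammation list a median of -0.01 (-0.03 with bounds) and a mean of 0.24 (adjusted p = 0.337), smooth muscle -0.44 (-0.09 with bounds, adjusted p = 0.573), hepatocyte -0.10 with camera upward (0.949), glycolysis -0.10 with camera upward (0.949) and reference genes 0.03 (0.75).

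Liver and stomach cells differed from each other in named genes, with 1 array each and hence no test. Liver cells were on slide 1 and stomach cells on slide 2, scanned on different days, so tissue cannot be told apart from slide and scan day. ANKRD1, a muscle ankyrin repeat protein, was 9.27 higher in liver cells on the log2 scale, the gelatinase gene MMP9 4.47 and IGF1 4.13, while ANXA8 (-4.69) and HP (-4.69) were lower in liver than in stomach cells. PODXL, not well above background in stomach cells, was at least 118.2-fold higher in liver cells, and the calcium channel gene CACNA1C, not well above background in liver cells, at least 62.9-fold lower. HP encodes haptoglobin, a plasma protein made by the liver. A total of 838 probes differed at least 4-fold, 386 higher in liver cells and 452 higher in stomach cells, and so did 19 named genes in each direction. The corresponding difference between the iPS lines was then set against it. Across the 28848 probes, liver minus stomach iPS cells correlated with liver minus stomach cells at r = 0.021 (rho = 0.029) at early and r = 0.013 (rho = 0.055) at late passage, and 50.5% (early) and 51.3% (late) of the 838 probes had the same sign. PODXL, for example, was at 7.29 and 7.30 in the early liver and stomach lines, and ANKRD1 at 1.51 and 0.50 early and at -0.53 and 0.71 late.

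The distance of each iPS array from ES cells was taken as 1 minus r with the mean of the ES arrays, with 1 array per line and passage and no test. It was 0.0176 for the liver line at passage 7 and 0.008 at passage 23, and 0.0126 for the stomach line at passage 6 and 0.0108 at passage 22. The ES lines lay 0.0115 from each other, and each iPS array lay between 0.1864 and 0.1999 from its own cells of origin. The value of 0.0115 is between single arrays, whereas a mean of 2 arrays carries less noise. The like values are therefore those to single ES arrays. Set against the ES arrays separately, the liver line went from 0.0182 to 0.0124 for ES replicate 1 and from 0.0226 to 0.0092 for ES replicate 2. The stomach line went from 0.0159 to 0.0109 for ES replicate 2 but from 0.0149 to 0.0165 for ES replicate 1, so that it was nearer at late passage to 1 ES line only. Late minus early differences correlated at r = 0.45 across probes between the lines. A total of 281 probes were at least 2-fold higher and 350 at least 2-fold lower at late passage in both lines, and 92 went opposite ways. Named genes at least 2-fold lower in both lines included EMP1 (-3.00 liver, -1.70 stomach), RLN1 (-2.48, -1.99) and HP (-1.82, -2.44), and genes at least 2-fold higher included TFPI (1.70, 1.94), ITGB3 (1.28, 1.42) and IL15 (1.11, 1.25), none of which passed the test.

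**Figure D4:**
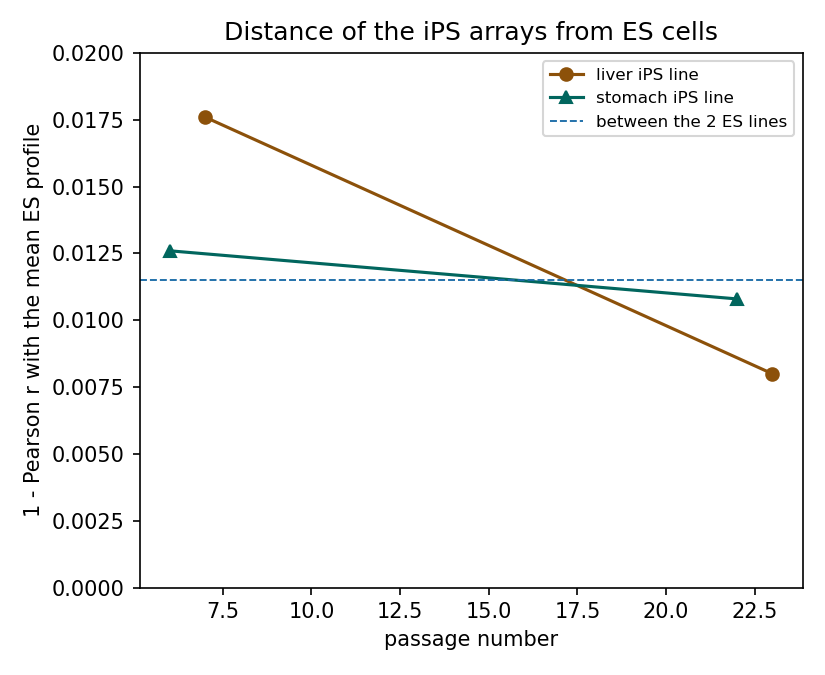
Distance of each iPS array from the mean ES profile (1 minus Pearson r across tested probes, no unit) against passage number, 1 point per array, with a dashed line at the distance between the ES lines, 0.0115. The dashed line is a distance between single arrays and is thus not a like measure to distances from a mean profile. The liver line lies at 0.0176 and 0.008 and the stomach line at 0.0126 and 0.0108.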

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

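The comparison of lineages was chosen after the data were seen. The difference between each iPS array and its own cells of origin was taken at both passages. Over the 507 named genes, the measured values of 26 went one way in the liver lineage and the other way in the stomach lineage, 16 of them with all 6 arrays of the lineages well above background. Only the 4 of these 26 genes that are described elsewhere in the results are given here. ANKRD1, well above background on all 6 arrays, was lower in the liver line (-3.55 early, -5.58 late) and higher in the stomach line (4.71 early, 4.93 late), a difference between lineages of -9.38. For HP, the haptoglobin gene, all arrays were well above background. It was higher in the liver line (2.70 early, 0.88 late) and lower in the stomach line (-1.66 early, -4.10 late), a difference between lineages of 4.67, with levels of -2.53 in liver cells and 2.16 in stomach cells. HBB2, a haemoglobin beta gene, was lower in the liver line than in liver cells (-0.32 early, -1.88 late). It was not well above background in stomach cells, so that only bounds hold for the stomach line, at least 3.46-fold higher early and at least 1.83-fold higher late, and the difference of -4.45 from the measured values is no estimate of size. GSC, a factor of the early mesoderm, was lower in the stomach line (-2.92 early, -3.96 late). It was not well above background in liver cells or in the late liver line, and its early level lay below the lowest signal well above background of the liver cells, so that no direction is shown for the liver lineage and the difference of 4.95 from the measured values has no support. Each such difference contains, with its sign reversed, the liver minus stomach difference of the cells of origin. That was 9.27 for ANKRD1 and -4.69 for HP. The iPS lines lay closer together, with ANKRD1 at 1.51 (liver) and 0.50 (stomach) early and at -0.53 and 0.71 late. HP was at 0.17 and 0.50 early and at -1.65 and -1.93 late. For ANKRD1 and HP the values thus mostly restate how the cells of origin differed. Each cell of origin had 1 array, and the differences between lineages were not tested.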

How the results depend on the processing

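Scan day as a block, the filter on at least 5 arrays, the runs without scaling and the distances without an ES array were chosen after seeing the data. The counts for iPS and ES against somatic cells stayed within 1.5 times their values under every alternative but 1, with each array left out giving 18241 to 19277 and 15033 to 18469. The exception was slide as a block, with 9916 probes for iPS against somatic cells. Since slide 3 held only stomach iPS arrays, the iPS values there rest on the liver line alone, with fewer degrees of freedom. The lower count thus does not show an effect of slide. For the 4 comparisons among pluripotent cells the cause of a changed count was not tested, except that filters test fewer probes and a left-out array leaves 1 array in a group. Counts with each array left out ranged from 0 to 35 for iPS against ES, 0 to 101 for late against early, 0 to 109 for early iPS against ES and 0 to 82 for late iPS against ES cells.

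Late against early iPS cells gave 6 probes with normexp (4 higher, 2 lower, 1 shared with the 8 of the chosen processing), 0 probes without the filter, with the filter on all 8 arrays, with the filter on at least 5 arrays, with the trended prior and with slide as a block, and 1 with scan day as a block. Early iPS against ES cells gave 6 with normexp, 0 with the filter on all 8 arrays, with the filter on at least 5 arrays and with slide as a block, and 19 with scan day. Of the 6 with normexp, 1 was among the 12 of the chosen processing. The trended prior gave 18, of which 6 were among the 12. Late iPS against ES cells gave 1 with quantile normalization and 0 with normexp, without the filter, with either filter on arrays, with the trended prior, with slide and with scan day. iPS against ES cells gave 6 with all 8 arrays as independent samples.

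With the cell of origin as a replicate block, late against early iPS cells gave 0 probes and iPS against somatic cells 20234. With line as a random replicate block, iPS against ES cells gave 6 probes, ES against somatic cells 18719, early iPS against ES cells 13 and late iPS against ES cells 6. Of the probes called without a block, 18763 of 19223 (iPS against somatic, cell of origin) and 18115 of 18447 (ES against somatic, line) were also called with it. The replicate block changed no other count by over 1.5 times. Of 24 list tests, 2 were called with the preset correlation, 0 with an estimated correlation and 11 with fry, which asks another question.

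The correlation of changes in iPS and ES cells was 0.916 and 0.907 with split controls. The origin correlation was 0.078 early and 0.042 late with normexp and 0.036 late with the filter on all 8 arrays. With that filter, the distances to ES cells were 0.0113 and 0.0072 for the early liver and stomach lines and 0.0048 and 0.0067 for the late ones, and the cause was not tested. Without an ES array the distances ranged from 0.0182 to 0.0226 (liver early), 0.0149 to 0.0159 (stomach early), 0.0092 to 0.0124 (liver late) and 0.0109 to 0.0165 (stomach late).

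Named genes kept direction and side of the threshold in 447 of their alternatives for iPS against somatic and 440 for ES against somatic cells, with 9 and 15 calls lost and 11 and 11 gained, and no call changed in the other comparisons. This tally leaves out the run without scaling, where further calls changed, and list members not named by the rule, such as CXCL8. The direction turned in 3 and 4 alternatives. With normexp it turned for ATP4A in iPS (-0.45) and in ES cells (-0.35), and for PGC in iPS (-0.52) and in ES cells (-0.43). With arrays left out, GSC ranged from -3.63 to 1.72 in iPS and from -2.97 to 2.38 in ES cells, and HBB2 from -3.23 to 2.17 in ES cells, each positive extreme against a somatic array that was not well above background. The offset of normexp raises dim signals alike, and whether this turned the sign was not tested. The signal over background limits what dim probes show: 22111 of 28848 tested probes were well above background on all 8 arrays.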

Other observations

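The gene families below, and the tests of slide, of noise and of remaining somatic cells for the passages, of 2-fold changes, of few changed probes and of bright probes alone, were chosen after the results were seen. All 4 measured subunits of the chaperonin CCT, which folds actin and tubulin, were higher in iPS than in somatic cells, namely CCT2 (1.28 ± 0.14 SE, adjusted p = 0.00115), CCT7 (1.23 ± 0.14), TCP1 (0.91 ± 0.15) and CCT6A (0.89 ± 0.16), and this direction held under each scaling. They were also all higher in ES cells, with a median of 0.99. Against the other named genes, camera gave adjusted p = 0.0534 over the 10 families and 4 comparisons, and adjusted p = 0.667 with an estimated correlation. Of 6 prostaglandin enzymes and receptors 5 fell in iPS cells, among them PTGS1 (-3.87 ± 0.31), the receptor gene PTGER4 (-4.36 ± 0.69) and PTGDS (-1.47 ± 0.33), with a median of -2.67 and camera adjusted p = 0.334 (0.667 with an estimated correlation). With quantile normalization 0 rose and 4 fell, with normexp 1 rose and 5 fell, and without scaling 1 rose and 3 fell.

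Of 11 potassium channel genes 4 were higher and 0 lower in iPS cells, among them KCNS3 and KCNK1, the last not well above background in somatic cells, but with normexp 1 was higher and 7 were lower, and without scaling 8 were higher and 0 lower (camera adjusted p = 0.167, 0.667 with an estimated correlation). Of 39 solute carrier genes 10 were higher and 16 lower, with normexp 4 higher and 25 lower, and without scaling 16 higher and 6 lower (camera adjusted p = 0.56). Of 4 matrix metalloproteinases 3 fell, MMP2, MMP9 (-4.67 ± 1.51) and MMP14 (-1.89 ± 0.32), while without scaling 2 fell and with normexp 4, and none rose under any scaling (camera adjusted p = 0.476). Of 8 calcium channel genes 1 was higher and 4 lower, with 2 higher and 3 lower without scaling. Of 15 translation factors 6 were higher and 4 lower, with 0 lower both with quantile normalization and without scaling. Of 12 phosphatase subunits 5 were higher and 4 lower, with 8 higher and 1 lower without scaling. Of 5 flavin monooxygenases 3 were lower and 0 higher, with 1 lower without scaling and all 5 lower with normexp. Of 3 anion channels of mitochondria 1 was higher and 0 lower, with all 3 higher with normexp and without scaling.

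Most tested probes differed between iPS and somatic cells. The scaling between arrays was argued against as the whole cause by 18773 calls with quantile normalization, and slide by the median absolute difference of the liver pair on 1 slide, which was 0.93 times that of the stomach pair on different slides. A block for slide lowered the count to 9916, but it rests the iPS values on the liver line alone, with fewer degrees of freedom. That count thus cannot decide on slide. Of the called probes 76.96% were well above background on all 8 arrays, which decides nothing on dim probes, since the share was 76.65% among tested probes and the counts allow no less than 64.95%. Dim probes as the source of most calls were argued against by the 70.35% called among the probes well above background on all 8 arrays when these were fitted alone. Cell type and culture medium change together, and which of them accounts for the calls stays open and untested.

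No probe differed between iPS and ES cells at the threshold with limma (2139 at an unadjusted p under 0.05). Too few lines stays open as the reason, and the spread used also contained the difference between liver and stomach cells. In simulated data with 200 changed probes, 73.3% of 4-fold and 6.12% of 2-fold changes were recovered, but with 9 changed probes 6.67% of 4-fold and 0% of 2-fold changes, so that the first share excludes nothing where few probes change. A total of 30 probes were at least 4-fold apart without overlap between the lines, with dim levels raised to the lowest signal well above background, and none was called. With 9 changed probes 51.1% of 8-fold changes were recovered, so that differences over 4-fold could also exist and not be called.

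Late iPS arrays lay nearer to the mean ES profile than early ones, except that the late stomach array lay farther from ES replicate 1. The early and late arrays of each line shared a slide and a scan day, so slide does not separate the passages within a line. The distance of the liver line to the ES array of its own slide fell by 0.0058. Independent noise was argued against by the correlation of 0.45 between the late minus early differences of the lines. Somatic cells left in the early cultures were argued against only at the share that the CAV1 level would need. CAV1 was chosen for this after its values were seen. The share was 4.479% in the liver and 4.258% in the stomach line. It predicts levels that the 371 probes at least 64-fold higher in somatic than in ES cells mostly did not reach. Of these, 357 lay below in the liver and 364 in the stomach line. The median observed minus predicted level was -2.9 in the liver line and -2.95 in the stomach line. With levels raised to the lowest signal well above background, over the probes predicted above it, the medians were -2.28 and -2.44. A smaller share of somatic cells was not tested. A shared adaptation of the lines to culture is a candidate explanation, for which the 2 lines and the absence of ES cells at several passages leave no test.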
